A study of Mus musculus with 6 samples.

How the data were processed

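Gene expression was measured by RNA sequencing in medullary thymic epithelial cells (mTEC) of C57BL/6 mice aged 4 weeks. mTEC are the thymic stromal cells that display tissue-restricted antigens to developing T cells. The genotypes were Copa+/+ (WT, 3 libraries) and CopaE241K/+ (MUT, 3 libraries). Copa encodes the alpha subunit of the COPI coat, which carries vesicles from the Golgi back to the endoplasmic reticulum, and E241K is the amino acid change that the genotype label gives for the mutant allele. Group and replicate number came from the sample titles. The labels do not say whether each library came from a separate animal or from a pool, so the p-values measure the spread between these libraries, part of which may be technical.

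Per the labels' protocols, total RNA was extracted with a column kit, converted to cDNA by Nugen Ovation amplification and made into libraries with Nextera XT. The protocols do not describe molecular identifiers, and amplified reads are not independent molecules, so floors and limits drawn from counts cover counting error only. The authors deposited a table of raw read counts per Ensembl gene ID, with 1 column per library and no normalization. Per the submitters' processing notes, STAR 2.4.2a, DESeq2 1.26.0 and the genome build GRCm38 were used, with no role stated for each. The counting program, annotation release and strand setting are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain.

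The deposited counts covered 43432 gene IDs, of which 42462 were matched to a symbol. Every row carried a gene ID and every sample column was used. Library totals ran from 19934513 to 23366238 counts. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 84.4. Coordinates are those of GENCODE M21 on GRCm38.

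The comparison was MUT minus WT. The test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment at 0.05, with no term other than genotype, and 17172 genes were tested. Standard errors are those of the log2 fold change. CPM values use TMM-scaled library sizes of the tested genes. A fold against a genotype with no counts was computed from the floor of 3 counts over that group.

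Before the data were examined, 29 gene lists were fixed from general knowledge: pathways, mTEC states, other cell types and signs of RNA quality. Of these, 28 formed 1 family for limma 3.58.1 camera, a test of whether list members shift relative to all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment. The list of sex-linked genes was given as library values only. A list's index is the mean log2 CPM (prior count 2) of its tested members in a library, compared by a two-sided exact permutation test over the 20 assignments of the libraries, whose smallest possible p is 0.1. The list symbols Mnda, Gbp5, Gbp6, Gbp10, Spt1 and Ahsp had no match in the table.

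Genes to be named were also set by rule before the data were examined. The rule named Copa, then up to 10 genes per direction with adjusted p under 0.05, non-overlapping genotypes and a mean CPM of at least 5. It then named the 3 members with the smallest p in each list past the threshold and the 1 member with the smallest p in every other list. No gene met the second part, and 37 genes were named. Genes outside the rule are said to have been chosen after their values were seen.

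Alternatives were the replicate number as a block, DESeq2 size factors, upper-quartile normalization, no filter on low counts, a stricter filter, DESeq2 1.42.0 with default settings and with the block, limma-voom, an adjusted p of 0.1, glmTreat against a 1.5-fold change, each library left out in turn, camera with an estimated correlation, fry, and list members held by no other list. Chosen after seeing the data were the myeloid and the thymocyte index as covariates, the tuft list without 5 genes that leukocytes also express, and DESeq2 with its independent filtering set to 0.05.

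The tests were tested on simulated data in 5 simulations of 17172 genes for this comparison, with 200 genes changed in each. edgeR recovered 9.97% of genes changed 4-fold, 40.7% of those changed 16-fold and 50.1% of those changed 64-fold, all with the right sign. DESeq2 recovered 21.7%, 61.7% and 77.0% of the same genes, with 73 of its 74 calls at 4-fold of the right sign. With no gene changed, edgeR called 0 genes in every simulation and DESeq2 called 56 to 99. A 1.5-fold shift of the 55 tested type I interferon list genes was called by camera in 5 of 5 simulations with the preset correlation and in 0 with an estimated one. The simulated genes varied independently of each other, so these simulations do not test the preset correlation.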

Results

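The series asked how gene expression in mTEC differs between mice heterozygous for the E241K allele of Copa and Copa+/+ mice of the same strain, and its title names STING and type I interferons in the thymus. Raw counts were available for 3 WT and 3 MUT libraries. The WT libraries 1, 2 and 3 held 20374756, 22880945 and 19934513 counts, and the MUT libraries 1, 2 and 3 held 21218363, 22888604 and 23366238. The number of genes with at least 1 count was 17174, 19558 and 21755 in WT and 19329, 20188 and 24774 in MUT. Mitochondrially encoded genes took 17.1%, 18.9% and 11.1% of the counts in WT and 16.04%, 21.3% and 9.14% in MUT. Spearman correlations between libraries ran from 0.712 to 0.906.

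Copa itself (ENSMUSG00000026553, chromosome 1, 172082529 to 172122330) was measured at 399.7 ± 151 CPM in WT and 347.6 ± 43.6 CPM in MUT (mean ± SD, n = 3 each, as for all CPM values given here). Its log2 fold change was -0.20 (SE 0.34), within the spread between libraries, and was 0.14 without WT replicate 1. The allele is a single amino acid change, so this count does not check the genotype. No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the lowest adjusted p was 0.999875. At an unadjusted p under 0.05 there were 597 genes, 279 higher and 318 lower in MUT, against 858.6 by chance. The genotypes did not overlap for 1606 genes, or 9.35% of those tested, and chance gives 10%. limma-voom called 0 genes, DESeq2 called 116, and edgeR without a filter on low counts called 73. In simulations with no gene changed DESeq2 made 56 to 99 calls, and edgeR without the filter was not simulated. Single-gene calls by DESeq2 or by unfiltered edgeR given below carry this limit. The spread between libraries was large: the biological coefficient of variation was 1.01, and the median SE of a log2 fold change, 1.03, exceeded the median absolute log2 fold change of 0.63.

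Genes induced by type I interferons were higher in MUT as a group. Of 55 tested members of the fixed list, 46 had a fitted value above 0, with a median log2 fold change of 0.65. Rsad2, which encodes the antiviral protein viperin (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), measured 25.1 ± 15.8 CPM in WT and 184.8 ± 54.8 CPM in MUT, a log2 fold change of 2.88 (SE 0.55). Oasl2, an oligoadenylate synthetase-like gene, measured 726.7 ± 107 and 1709 ± 125 CPM (1.23, SE 0.26), and its relative Oasl1 85.97 ± 39.8 and 319 ± 102 CPM (1.89, SE 0.45). All 3 MUT libraries lay above all 3 WT libraries for each of these genes, and for 18 members of the list, with none in the opposite order. The list's camera adjusted p was 3.2e-12 with the preset correlation, and the adjusted p = 0.24 with an estimated correlation of 0.14. With an estimated correlation the simulated 1.5-fold shift of this list was not called either. Over all genes tested 0 members passed edgeR's test, and adjusted over the list alone 7 did, all higher: those 3 and, chosen after their values were seen, Ifit1, Herc6, Ifit2 and Usp18. Over all genes, edgeR without a filter called Rsad2 (adjusted p 6.2e-05), Oasl1 (0.0069) and Oasl2 (0.034), and DESeq2 called Rsad2 (0.0063) and Ifit2 (0.048). False calls of the unfiltered fit were not measured, and DESeq2 made calls in simulations without an effect. The count of 7 was 1 without WT replicate 3 or without MUT replicate 1, 2 without MUT replicate 2 and 4 without WT replicate 2. Camera with the preset correlation called lists in other groupings of these libraries too: 6 of the 9 other splits into 3 and 3 called at least 4 of the 28 lists, and 1 of them gave the type I interferon list p = 1.3e-10 against 1.1e-13 for the genotypes. Every other split has 2 MUT libraries on 1 side, so the genotype difference enters it in part, and that side was the higher for this list in 7 of the 9, including that split. Each of the 6 splits that called lists put 2 libraries of the same replicate number on 1 side. The remaining splits kept same-numbered libraries apart and called 0 lists.

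**Figure D1:**
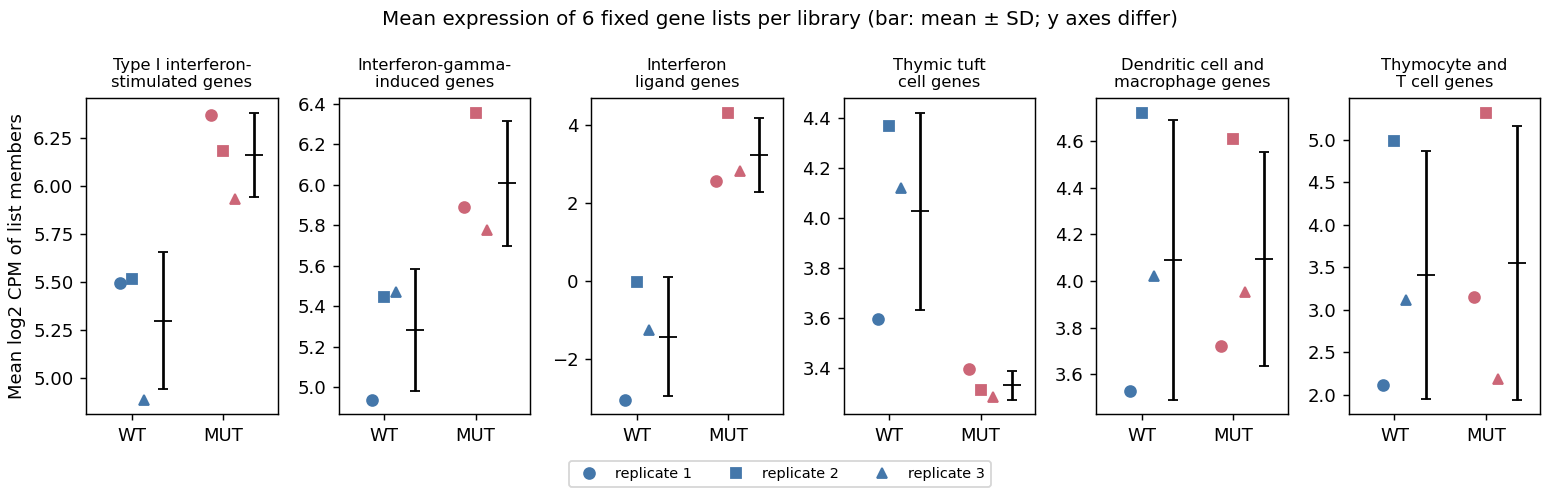
Mean log2 CPM of the tested members of 6 fixed gene lists (y axes, which differ between panels) in each WT and MUT library; points are libraries, and the bar beside them is the mean ± SD of 3. The type I interferon index lies at 5.30 ± 0.36 in WT and 6.16 ± 0.22 in MUT without overlap, the tuft index at 4.03 ± 0.39 and 3.33 ± 0.06 without overlap, and the dendritic cell and macrophage index at 4.09 ± 0.60 and 4.09 ± 0.46.

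The list of genes induced by interferon-gamma, which includes guanylate-binding proteins and chemokines, was also higher in MUT. Whether its members rose through interferon-gamma or another interferon was not tested. Of 22 tested members, 20 had a fitted value above 0, with a median log2 fold change of 0.70. The camera adjusted p was 6.7e-05, and the adjusted p = 0.24 with an estimated correlation. No member passed edgeR's test over all genes, and 0 did adjusted over the list alone. The guanylate-binding protein gene Gbp7 measured 22.3 ± 12.1 CPM in WT and 62.9 ± 20.5 CPM in MUT (log2 fold change 1.495, SE 0.62). Genes for the T cell attractants Cxcl9 and Cxcl10 measured 706 ± 193 and 1233 ± 486 CPM (0.80, SE 0.34, but 0.43 without MUT replicate 2), and 910.0 ± 198 and 1394 ± 208 CPM (0.61, SE 0.28).

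The interferon-beta and interferon-lambda genes themselves were counted more often in MUT. Ifnb1, the interferon-beta gene (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), had 0 counts in each of the 3 WT libraries and 86, 510 and 139 counts in MUT libraries 1, 2 and 3. Pooled over libraries it was at least 215.5-fold higher in MUT, computed from a floor of 3 counts over the WT group, and at least 94.2-fold without MUT library 2. Its adjusted p over all genes was 0.999875 in edgeR, 0.042 in edgeR without a filter, 4.6e-05 in DESeq2 and 0.00033 in DESeq2 on the genes edgeR tested, and it was the 1 list member that passed adjusted over the list alone. No other gene had 0 counts in WT and at least 86 in every MUT library, and among other choices of 3 libraries up to 7 genes were counted in this all-or-none way. The interferon-lambda genes Ifnl3 and Ifnl2 measured 3.13 ± 4.22 and 22.4 ± 16.2 CPM, and 0.57 ± 0.62 and 6.06 ± 2.82 CPM, with log2 fold changes of 2.84 (SE 1.38) and 3.39 (SE 2.04). WT library 2 held 169 of the WT counts of Ifnl3, with 2 and 30 in WT libraries 1 and 3, and without it the log2 fold change was 4.93. These are near-identical neighbours on chromosome 7 whose reads the counting could have divided, so their separate values are uncertain. The 3 tested ligand genes had a camera adjusted p of 3.1e-05, and the adjusted p = 0.24 with an estimated correlation. The count filter asks for enough counts in 3 libraries, which none of the 3 genes had in WT alone. Ifnb1 passed through its MUT counts alone, and Ifnl3 (2, 169 and 30 WT counts) and Ifnl2 (0, 26 and 11) needed MUT counts too. The list's p values, its index and the adjustment over the list alone therefore rest on genes let in through MUT. Without the filter the list's camera adjusted p was 0.0035. The 3 tested genes had a median log2 fold change of 3.39, also with Ifnb1 set at its bound. The other 18 listed ligand genes were counted too rarely to be tested. Among the interferon-alpha genes, Ifna4 had 32 and 29 counts in MUT libraries 2 and 3 and 0 in the others, and Ifna6 had 45 counts in WT library 3 alone. The interferon-gamma gene Ifng had 0, 10 and 2 counts in WT libraries 1, 2 and 3. In MUT libraries 1, 2 and 3 it had 0, 2 and 11.

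Genes of thymic tuft cells, chemosensory cells of the medulla, were lower in MUT as a group. Of 29 tested members, 4 had a fitted value above 0, with a median log2 fold change of -0.97. The camera adjusted p was 6.7e-05, and the adjusted p = 0.21 with an estimated correlation of -0.016. No member passed edgeR's test over all genes, and 0 passed adjusted over the list alone; without a filter on low counts edgeR called Dclk1 (adjusted p 0.019) and Sh2d7 (0.034). The tuft cell kinase gene Dclk1 measured 142.8 ± 73.9 CPM in WT and 30.4 ± 27.3 CPM in MUT (log2 fold change -2.23, SE 0.79). Sh2d7 measured 74.8 ± 104 and 10.3 ± 6.04 CPM (-2.86, SE 1.05), and Lrmp 155.6 ± 137 and 52.5 ± 11.6 CPM (-1.57, SE 0.60). WT replicate 1 held the highest value of both, and without it their log2 fold changes were -0.54 and -0.58.

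**Figure D2:**
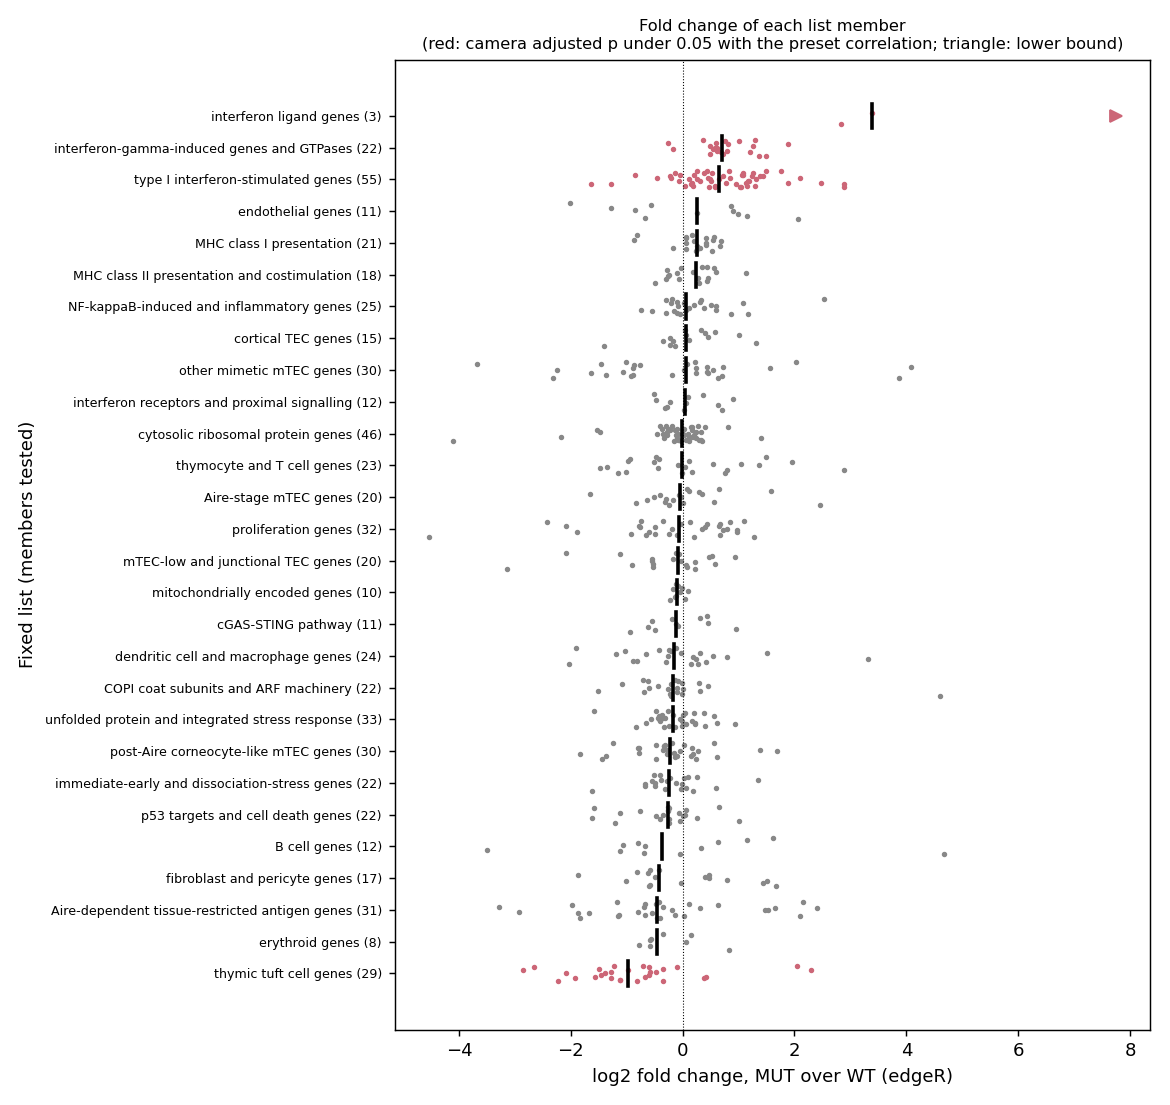
log2 fold change of MUT over WT (x axis) for each tested member of the 28 fixed lists (y axis, members tested in parentheses), with a black bar at each list's median and lists past the camera threshold with the preset correlation in red. The triangle is the lower bound of Ifnb1 from a floor of 3 counts; 46 of 55 type I interferon list members lie above 0, and 4 of 29 tuft members do.

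Other mTEC states did not pass the main list test. The Aire-stage list, named for the regulator of antigen display, had a median log2 fold change of -0.05 (camera adjusted p 0.87). Its member Ccl5, a chemokine gene that interferon also induces (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), had the smallest p of all genes tested and was the 1 member to pass adjusted over the list alone. Ccl5 measured 239.4 ± 98.7 CPM in WT and 1312 ± 647 CPM in MUT (log2 fold change 2.45, SE 0.45). Over all genes its adjusted p was 0.999875 in edgeR and 0.029 in DESeq2. Without a filter, a fit that was not simulated, edgeR gave an adjusted p of 1.0e-08 at an almost unchanged log2 fold change of 2.46. Aire-dependent antigen genes had a median of -0.45 with 10 of 31 members above 0 (camera adjusted p 0.11). That list passed, as lower in MUT, in limma-voom (0.032), without a filter (0.033), without WT replicate 1 (0.033) and without MUT replicate 2 (0.024). Its member Fabp2 measured 85.1 ± 78.8 and 23.9 ± 11.02 CPM, with 175.6 CPM in WT replicate 2, and without that library the log2 fold change went from -1.83 to -0.75. The mTEC-low list (median -0.09, camera adjusted p 0.68) included Ackr4, at 17.9 ± 3.75 and 2.01 ± 1.41 CPM. The corneocyte-like list (-0.23, camera adjusted p 0.32, but 0.0037 and lower without WT replicate 1) included Ly6d, at 140.0 ± 18.4 and 51.4 ± 6.07 CPM. The list of other mimetic cells, which express programmes of peripheral tissues (0.05, camera adjusted p 0.87), included the muscle regulator Myog, at 1.80 ± 0.72 and 26.3 ± 16.96 CPM. None of Fabp2, Ackr4, Ly6d and Myog passed edgeR's test over all genes, while DESeq2 called Ackr4 (adjusted p 0.039), Ly6d (0.024) and Myog (0.00046). On the genes edgeR tested DESeq2 kept Myog (0.019) and lost Ackr4 (0.22) and Ly6d (0.15). Proliferation genes (-0.06, camera adjusted p 0.87) included Ccnb2, where WT replicate 2 alone held 1169 CPM; without it the log2 fold change went from -4.54 to -1.11.

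Pathway lists beside the interferon groups did not pass the main test either. MHC class I presentation genes had 18 of 21 members above 0 and a median log2 fold change of 0.26 (camera adjusted p 0.21, and 0.032 in limma-voom), with H2-Q7 at 249 ± 45.9 CPM in WT and 357.4 ± 46.0 CPM in MUT. MHC class II genes had a median of 0.24 (camera adjusted p 0.71), and Cd74, the invariant chain, had a log2 fold change of -0.50 (SE 0.30), or -0.31 without WT replicate 1, -0.29 without MUT replicate 3 and -0.78 without MUT replicate 1. The cGAS-STING list had a median of -0.12 (camera adjusted p 0.87), with the kinase Tbk1 at -0.93 (SE 0.53). Interferon receptor and signalling genes had a median of 0.04 (camera adjusted p 0.87), with Jak2 at 0.70 (SE 0.40), or 0.44 without WT replicate 1. The list of COPI coat subunits and ARF machinery had a median of -0.17 with 5 of 22 members above 0 (camera adjusted p 0.28). By fry it was lower in MUT at an unadjusted p of 0.010, with an adjusted p of 0.095. Its member Kdelr3 owed its fitted 4.60 (SE 1.86) to MUT replicate 1, without which it was 1.32. The unfolded protein response list had a median of -0.17 (camera adjusted p 0.32), with Creld2 at -0.83 (SE 0.44), or -0.34 without WT replicate 1. Its index lay at 6.80 ± 0.07 in WT and 6.55 ± 0.17 in MUT without overlap (exact p = 0.1). NF-kappaB targets had a median of 0.06 (camera adjusted p 0.63), with Ccl2 at 1.17 (SE 0.54), or 1.76 without WT replicate 2, and p53 and cell death genes had -0.25 (camera adjusted p 0.21), with Fas at -1.21 (SE 0.59).

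Markers of other cell types did not pass the main list test. The thymocyte index was 3.40 ± 1.46 in WT and 3.55 ± 1.61 in MUT (exact p = 0.7), and the dendritic cell and macrophage index 4.09 ± 0.60 and 4.09 ± 0.46 (exact p = 1). Camera adjusted p values were 0.92 for thymocytes (Cd4 at 0.75, SE 0.47, but 0.45 without MUT replicate 2 and 0.46 without WT replicate 1), 0.87 for dendritic cells and macrophages (Adgre1 at -2.04, SE 0.95), 0.87 for B cells (Vpreb3 at 4.67, SE 2.46, but 8.92 without WT replicate 3) and 0.95 for cortical epithelium (Cxcl12 at -1.40, SE 0.83, but -0.77 without WT replicate 1). For fibroblasts and pericytes it was 0.87 (Rgs5 at -0.61, SE 0.31, but -0.30 without WT replicate 1), for endothelium 0.87 (Esam at 2.05, SE 1.45) and for erythroid cells 0.92 (Hba-a2 at 0.82, SE 1.07, but 0.35 without MUT replicate 2 and 1.32 without MUT replicate 3). Among signs of RNA quality, it was 0.32 for immediate-early and dissociation genes (Ier3 at -1.62, SE 0.68, but -0.40 without WT replicate 1), 0.63 for mitochondrially encoded genes (mt-Nd6 at -0.22, SE 0.36, but 0.08 without MUT replicate 3, 0.02 without WT replicate 1 and -0.63 without MUT replicate 2) and 0.68 for ribosomal protein genes. For the B cell, erythroid and Aire-stage lists the median lay below 0 and the camera direction above, and for the cortical and other mimetic lists the reverse held. The ribosomal member with the smallest p, Rpl19, held 262 CPM in WT replicate 1 and at most 8.05 CPM in any other library.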

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

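The covariates, the shortened tuft list and the DESeq2 fits with filtering at 0.05 and on the genes edgeR tested were chosen after seeing the data. The count of 0 genes held under DESeq2 size factors, upper-quartile normalization, the stricter filter, limma-voom, an adjusted p of 0.1, glmTreat, both covariates and with any 1 library left out. It became 116 with DESeq2 (78 higher, 38 lower), 122 with its filtering at 0.05 (82 and 40), 35 with DESeq2 on the genes edgeR tested (25 and 10), and 73 without a filter on low counts (31 and 42). In self-tests DESeq2 made up to 99 calls without an effect. The self-tests ran edgeR with its filter only, so its false calls without the filter are unknown, and the cause of the unfiltered calls was not tested. The median log2 fold change of all genes moved from -0.01 to 0.16 without the filter, 0.16 with DESeq2 and 0.20 with DESeq2 and the block.

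The labels do not say that a replicate number marks a shared batch, and same-numbered libraries deviated together with correlations of 0.059 to 0.13. Yet 6 of 6 libraries correlated best across genotypes with their own number, and the source names of same-numbered libraries share an ending whose meaning the labels do not give. With the replicate block edgeR called 1 gene, Ccl5 (adjusted p 0.031; 1 higher, 0 lower), and DESeq2 302 (182 higher, 120 lower), among them Ccl5 (0.00035) and Dclk1 (0.014); the type I interferon list had an adjusted p of 9.7e-13, and the block changed no list call.

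The type I interferon list lost its call with an estimated correlation (adjusted p 0.24) and with fry (0.15). Its unadjusted p was 0.035 by camera with an estimated correlation and 0.027 by fry. In simulations of independent genes, camera with an estimated correlation called a 1.5-fold shift of this list in 0 of 5. Losing the call there therefore cannot decide whether correlation between members explains the result. The list kept its call in every other setting run, from 3.6e-17 without WT replicate 1 to 0.0020 without WT replicate 3. The other lists called, 3 at first, were 0 with an estimated correlation, 0 with fry, 5 with limma-voom, and 3 to 6 with 1 library left out, 5 without WT replicate 1 and 6 without MUT replicate 2. List members passing over the list alone ranged from 1 (without WT replicate 3 or MUT replicate 1) to 6 with 1 library left out, Copa's log2 fold change from -0.42 to 0.14 and mt-Nd6's from -0.63 to 0.077. Of 36 named genes other than Copa, 16 had a log2 fold change that fell by over 1.5 times or turned with 1 library left out, 11 of them through WT replicate 1, and 6 had one that grew by over 1.5 times, 3 of them among the 16. The ligand list's adjusted p was 0.0035 without the filter. Lists whose index separated the genotypes, 5 of 28 at first (type I, gamma, ligand, unfolded protein response and tuft), ranged from 2 without WT replicate 1 to 6 without WT replicate 2. For each of the 5 the exact permutation p was 0.1, the smallest possible, and chance alone separates 10% of lists at 3 against 3 libraries. Without the 5 leukocyte-expressed genes the tuft list's adjusted p was 0.000349.

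Lists that were not called changed direction in places. With 1 library left out their adjusted p ran from 0.59 to 0.97 for interferon signalling, 0.27 to 0.999 for NF-kappaB, 0.41 to 0.95 for MHC class II, 0.31 to 0.9999 for Aire-stage, 0.13 to 0.87 for mTEC-low and 0.49 to 0.9999 for other mimetic genes. It ran from 0.29 to 0.97 for cortical epithelium, 0.65 to 0.97 for proliferation, 0.00036 to 0.82 for thymocytes, 0.47 to 0.98 for B cells and 0.058 to 0.82 for myeloid genes. For endothelium the range was 0.24 to 0.93, for erythroid genes 0.23 to 0.92, for immediate-early genes 0.0018 to 0.81, for mitochondrial genes 0.0035 to 0.9999 and for ribosomal genes 0.055 to 0.85. Lists not called at first passed with 1 library left out: thymocyte and mitochondrial genes without MUT replicate 2, Aire-dependent genes without WT replicate 1 (0.033) or MUT replicate 2 (0.024), corneocyte-like genes without WT replicate 1 (0.0037), and immediate-early genes without MUT replicate 1 or WT replicate 3 (0.024). Aire-dependent genes also passed in limma-voom (0.032) and without a filter (0.033), and MHC class I in limma-voom (0.032). Estimated correlations between members were 0.54 for thymocyte, 0.89 for mitochondrial and 0.35 for immediate-early genes. They were 0.14 for corneocyte-like and 0.0072 for Aire-dependent genes. Where the estimate lies far above the preset 0.01, camera with the preset correlation can give p values that are too small. Direction also turned for cortical epithelium under upper quartile (0.96) and fry (0.99), for thymocytes under fry (0.99) and the myeloid covariate (0.91), and for interferon signalling, B cell and erythroid genes without the filter (0.99 each). The cause of these turns was not tested. Depth limits genes near the floor of 3 counts, 0.049 CPM over the WT group. Of 12737 genes with a mean CPM of at least 5, which is 99.7 counts in the library with the lowest total, 780 (6.12%) had no count in at least 1 library, and the cause of these zeros was not tested.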

Other observations

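Chosen after the result was seen were the tests of leukocyte RNA, of 1 WT library with a high tuft signal, of dilution, of simulated DESeq2 calls, of the type I list against the gamma list, and the counts of splits for the number of lists, for list members, and for the gamma and ligand lists. Among the genes with the smallest p, all chosen after their values were seen and none past the edgeR threshold, Igf2, an insulin-like growth factor gene, measured 139.7 ± 19.6 CPM in WT and 45.5 ± 11.4 CPM in MUT (SD, n = 3 each). Chil1 measured 147.7 ± 52.6 and 45.4 ± 5.52 CPM, and Mocs1 327.6 ± 105 and 87.3 ± 35.8 CPM. The T cell growth factor gene Il2 was at most 0.094 CPM in any WT library and 24.5, 29.3 and 1.63 CPM in MUT libraries 1, 2 and 3. Xist was measured at 1186 to 1711 CPM across the 6 libraries, and the Y-linked genes Ddx3y and Eif2s3y were counted in all 6 as well, at 10.5 to 52.8 and 6.38 to 65.0 CPM. These values do not mark any library as RNA of 1 sex alone, and whether the libraries were pools was not tested.

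The first pattern is the higher interferon groups in MUT. More leukocyte RNA there would raise leukocyte indices too, but MUT had the higher myeloid index in 4 of 9 pairs of a MUT and a WT library. It had the higher thymocyte index in 6 and the higher B cell index in 5, against 9 of 9 for the interferon index. These pairs ignore the replicate number. In libraries 1, 2 and 3 the myeloid index was 3.53, 4.72 and 4.02 in WT and 3.72, 4.61 and 3.95 in MUT. The thymocyte index was 2.11, 4.99 and 3.11 in WT and 3.14, 5.32 and 2.18 in MUT. The B cell index was 0.95, 2.59 and 2.42 in WT and 1.86, 3.56 and 2.09 in MUT. Ptprc stood out in 1 library (37.5, 384 and 26.02 CPM in MUT libraries 1, 2 and 3, against 24.3, 104 and 60.5 CPM in WT), while Laptm5 and Lyz2 ran from 660 to 1146.7 CPM and 384.0 to 635.9 CPM in MUT and from 742 to 1251 CPM and 387 to 721.6 CPM in WT. The indices are means over many markers and do not exclude a small subset of leukocytes. Il2 and Ccl5 were higher in every MUT library than in any WT library, and which cells expressed them was not tested. Bias by expression, GC content or transcript length is argued against by matched lists: the list's median stood at percentile 100 of 10000 lists matched on all 3. With 10 splits of 6 libraries no share under 0.05 can be reached; the p of the type I list was 1.1e-13 for the genotypes and at best 1.3e-10 in another split, so 1 of 10 splits, the real one, had a p as small, and the same 1 of 10 held for the gamma list (7.4e-06, best other 0.0013), the ligand list (2.2e-06, best other 0.0093, on genes the count filter let in partly through their MUT counts) and the 7 members called over the list alone (highest other 1). As many lists as the real 4 were called in 7 of 10 splits, with up to 10 in another. The other splits that called lists all put same-numbered libraries on 1 side. Splits by WT 1, WT 2 and MUT 3, by WT 1, WT 3 and MUT 2, and by WT 1, MUT 2 and MUT 3 kept them apart. Each called 0 lists, with a camera p of the type I list of 0.063, 0.017 and 0.0099. The genotype difference enters the other splits in part, since each has 2 MUT libraries on 1 side. With the replicate block the type I list kept its call (camera adjusted p 9.7e-13). Each replicate number has 1 WT and 1 MUT library, so a difference between numbers would fall on both genotypes alike. Together with the call kept under the block, this argues against replicate number as the source of the type I list's call. Other structure among the libraries that the preset correlation does not cover stays open. An interferon response of the mutant mTEC remains a hypothesis.

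Ifnb1 was the 1 gene with no count in WT and at least 86 counts in every MUT library; among the 18 other choices of 3 libraries the median was 0 genes and the highest 7, so random amplification of few starting molecules was not excluded. A larger rise of genes listed as type I-induced than of those listed under gamma was not seen: the medians differed by -0.045 (permutation p = 0.87 over genes, which are not independent replicates). No test showed that members of either list respond to 1 interferon only, so this comparison cannot tell which interferon acted.

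The second pattern is the lower tuft group in MUT. By camera with the preset correlation it kept an adjusted p of 0.00091 without WT replicate 2, the WT library with the highest tuft index. At the weakest, without MUT replicate 3, the adjusted p was 0.016. That test also called lists in other splits, so these p values alone do not exclude 1 high library. The tuft index was 3.60, 4.37 and 4.12 in WT libraries 1, 2 and 3 and 3.40, 3.32 and 3.28 in MUT. Every WT library lay above every MUT library, which argues against 1 high WT library as the whole source. Dilution of all mTEC would lower other mTEC genes alike. But the 80 Aire-stage, corneocyte-like and other mimetic genes, pooled after the data were seen, had a median log2 fold change of -0.15. Its 95% bootstrap bounds over genes were -0.31 and 0.08. All 5 mTEC state lists pooled had -0.18 (-0.36 and -0.03), against -0.97 (-1.29 and -0.59) for tuft genes, at percentile 0 of 10000 matched lists. Genes of the same 6 libraries are not independent replicates, so these bounds do not measure the spread between libraries. The Aire-dependent list alone, at -0.45 (-0.69 and -0.14), had bounds that overlap those of the tuft list, so a fall shared by both was not excluded. The splits are again too few for a share under 0.05: the p was 9.5e-06 for the genotypes and at best 0.0066 in another split, as small in 1 of 10. A smaller share of tuft cells and lower expression per tuft cell both remain open and untested; with an estimated correlation the call ended (adjusted p 0.21) although that correlation was -0.016, since camera then uses the 4 residual degrees of freedom.

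The third pattern is the 116 genes that DESeq2 called where edgeR called 0, with only 2 in the type I interferon list and 0 in the tuft list. False calls at this spread are a candidate explanation: simulations without any effect over the 17172 genes edgeR tested gave a median of 81 DESeq2 calls (56 to 99), but DESeq2 made 35 calls on those genes alone, fewer than any simulation, so the simulations can overstate false calls. Of the 116 genes, 46 (39.7%) had over 66.7% of the higher genotype's CPM in 1 library against 25.5% of all genes tested by edgeR, but 25 of the 116, with 20 of the 46, were not tested by edgeR, and the other 91 had 26 (28.6%). Of the 35 calls 17 did (48.6%), so how many calls rest on 1 library stays open. For edgeR the real count was 0, so all 10 of 10 splits necessarily gave as many (highest other 0), which says nothing about the genotypes.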
